A study of Mus musculus with 8 samples.

How the data were processed

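Single-nucleus RNA was measured in marrow-flushed femurs and tibiae of male and female C57BL/6 mice aged 5 months and fasted for 4 h, per the labels. Nuclei were tagged with hashtag antibodies, sorted by flow cytometry and loaded on a droplet platform that reads transcript 3' ends, per the labels. The 8 GEO libraries are 4 expression libraries and 4 hashtag libraries of the same nuclei. The expression libraries are batch 1 and pools 2, 3 and 4 of batch 2. Each holds 1 female and 1 male hashed sample, which makes 4 samples per sex. The labels do not say whether a hashed sample is 1 mouse or several, or whether the pools hold different animals, so p-values measure only the spread between these samples.

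The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and barcode, without normalisation. The authors' tables give, for each nucleus, its UMI counts, its number of genes with a UMI, its percent of mitochondrial UMIs, its hashtag and its cluster number. Cell Ranger 9.0.1, R 4.3.1 and Seurat with the mouse genome GRCm39 were used, per the submitters' processing notes, which do not state the order or role of each. The tables list only nuclei with a single hashtag that the deposited mapping assigns to a sample. Of the 4 hashtags per library, 2 had no sample in that mapping and were not used in any comparison. Matrices of batch 1 and of pool 3 were analysed, with 33696 genes. The tables of all 4 expression libraries were used for cell type shares. UMI totals in the tables equalled the matrix sums in 72.5% of batch 1 nuclei and 79.7% of pool 3 nuclei, and differed by at most 13 and 19 UMIs elsewhere. No further filter was applied to the listed nuclei, whose lowest total was 500 UMIs and whose highest mitochondrial share was 14.2%. Because the gene annotation at hand was of another genome build, genes are given by symbol without coordinates.

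Cell type names were not in the tables used here. The nuclei with counts were therefore clustered jointly in scanpy 1.11.5 with counts scaled to 10000 per nucleus, log1p, 2000 variable genes chosen by library, 30 principal components, 15 neighbours and Leiden resolution 1 with seed 0 (leidenalg 0.10.2, igraph 0.11.9). A cluster took the name of the marker list with the highest mean fold when at least 3 of that list's genes stood at least 1 log2 unit above the other clusters, with 20 CPM (UMI counts relative to the total of the summed nuclei, in the usual CPM unit) added to each value. A cluster was left unnamed where another list had more genes among its 10 leading genes, or where it lacked markers and its median depth was under 1/3 of the sample's own. The 23 marker lists hold 189 genes. Of 29 joint clusters, 26 were named and 3 were not. The authors' clusters, 18 in each batch, were named by the same rule and were used for shares, since only they cover 4 libraries. Scrublet marked 4 of 3993 nuclei (0.100%) in batch 1 and 15 of 4745 (0.316%) in pool 3, so leaving those out removed few nuclei.

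Counts were summed per hashed sample and cell type where a sample had at least 20 nuclei of the type. Sums were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment, and an adjusted p under 0.05 counted as passing. Female and male osteocyte sums were compared with library as a term, which leaves 1 residual degree of freedom over 4 samples. Osteocytes were compared with osteoblasts, and with the mean of the other types that had enough nuclei, with the sample as a block. The difference between the sex effects in osteocyte and erythroid nuclei was tested as an interaction with the sample as a block. Erythroid nuclei were taken because they were the most numerous other type. Fixed gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 on log CPM with a prior count of 2, again with an estimated correlation, and with fry. The 19 lists hold 240 genes, of which 7 were not found by symbol. They are Y-linked, X inactivation and escape, osteocyte identity, matrix and mineralization, WNT pathway and antagonists, osteoclast regulation, perilacunar remodeling, mechanosensing and gap junctions, hormone and growth factor receptors, dendrite, cytoskeleton and axon guidance, fasting and FOXO response, circadian clock, immediate early and dissociation stress, senescence, hypoxia and glycolysis, oxidative phosphorylation (nuclear), erythroid RNA, granulocyte RNA, and muscle RNA. Gene levels of tested sums are CPM after TMM scaling within each comparison, with the standard deviation (SD) over samples. The same sum thus has different CPM in different comparisons. Retnlg in male osteocytes of batch 1 stood at 1160 CPM in the sex comparison and at 614 CPM in the interaction test. CPM of whole samples and of barcodes outside the authors' tables were not TMM scaled. Fold changes are fitted log2 values. Their standard error (SE) was worked back from the F statistic, as the absolute value over the square root of F, and is unreliable near 0.

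Shares of cell types are percent of the listed nuclei of a sample, with 95% exact Clopper-Pearson intervals that cover counting error only. Female and male shares were compared by an exact two-sided permutation test of the mean difference with sex exchanged within libraries. The 16 arrangements give a smallest p of 0.125, so no share could pass the threshold. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

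The groups, tests, marker lists, fixed lists and the rule for naming genes were chosen before the data were examined. That rule names, per comparison, the 10 genes with the lowest adjusted p in each direction among those passing, outside the sex-linked lists. It adds up to 4 passing members of each fixed list by adjusted p, or the 2 with the lowest p where none passes. Dmp1, Sost, Phex, Mepe, Fgf23, Pdpn, Dkk1, Tnfsf11, Tnfrsf11b, Esr1 and 1 more gene are always named. This last gene and 1 from a fixed list are not reported here or in the sensitivity table, but stayed in the fits and list counts. Where fewer than 5 genes pass outside the sex-linked lists, the 5 with the lowest p in each direction are given as values. Other named genes were chosen after their values were seen. Some genes that the rule names are not printed, above all against other types, and no preset rule chose which to print.

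The tests were tried on simulated counts with a dispersion of 0.1 and 200 changed genes, after they had first been fitted to the real counts. For sex in osteocytes, edgeR found 0% of 2-fold and 5% of 4-fold changes with 0 false calls, so it had little power at that dispersion. The dispersion was the same for every gene and was not matched to the real counts. For osteocytes against osteoblasts it found 9.20% and 76.9%, with 5 false among 83 calls. For osteocytes against other types it found 32.9% and 92.5%, with 1 false among 87 calls. The interaction test found 1.03% and 2.02% with 0 false calls. A planted list of 20 genes gave a camera p of 1.54e-08 and a fry p of 0.0459 in edgeR log CPM.

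Alternatives tried were DESeq2 1.42.0 size factors in edgeR, the DESeq2 Wald test, no filter on low counts, no library term, a library term in place of the sample block, at least 50 nuclei per sample, only nuclei with at least 1000 UMIs, leaving out Scrublet doublets, equal numbers of nuclei per sample, another denominator for shares, permutation over all samples, and leaving out each sample in turn. Osteocyte nuclei by the authors' clusters, shares from the joint clusters, shares from the authors' clusters in the libraries with counts, shares with unnamed clusters counted under their closest list, and the sex test in other types with 2 samples per sex in place of the 3 first asked for were added after seeing the data. An unnamed cluster of the authors was counted as non-haematopoietic only where at least 3 markers of such a type were raised, which held for the batch 2 cluster closest to osteoblasts alone, a rule settled after shares had been seen. Old against young osteocytes, osteocyte subtypes, each library alone and an age term were not run, since the tables give 1 age and no subtypes and each library holds 1 sample per sex. The 24 splits behind the comparison with other types are a draw from a larger number.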

Results

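The nuclei listed by the authors numbered 22443, with 3993 in batch 1 and 18450 in batch 2. They came from 8 hashed samples, 1 female and 1 male in each of 4 expression libraries. Batch 1 held 7914509 UMIs in 1850 female nuclei and 8411206 in 2143 male nuclei. Pool 2 held 34596189 in 3508 female and 31555749 in 3062 male nuclei. Pool 3 held 15337311 in 1884 female and 22956950 in 2861 male nuclei. Pool 4 held 23518041 in 3650 female and 23426700 in 3485 male nuclei. Median depth per nucleus lay between 3032 and 7987.5 UMIs. Gene counts of 8738 nuclei, from batch 1 and pool 3, entered the expression comparisons, with 2 samples per sex. The stated purpose was to recover many osteocyte nuclei, the cells embedded in bone matrix, and to chart their expression in both sexes.

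Xist, the RNA that silences an X chromosome, stood at 1188 CPM in the batch 1 female sample and 2387 CPM in the pool 3 female sample, against 10.7 and 12.5 CPM in the male samples. At least 1 UMI of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y was found in 63.8% of batch 1 and 77.2% of pool 3 male nuclei. The same genes, which females lack, gave a UMI in 1.14% and 4.09% of female nuclei. Median depth in these samples was 3405 UMIs (female) and 3032 UMIs (male) in batch 1, and 6365 and 6088 in pool 3. Each of these 4 samples thus matched its labelled sex.

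Osteocyte-like nuclei made up 22.6% ± 11.6 (SD, n = 4) of the nuclei in female samples and 7.47% ± 5.33 (SD, n = 4) in male samples, a difference of 15.2 points (SE 4.86). These are the nuclei in clusters raised in Sost, which encodes the bone formation inhibitor sclerostin, Mepe and Phex, which act in mineralization and phosphate balance, and Dmp1, a matrix protein. The female share was the higher in 4 of 4 libraries. In batch 1 it was 5.62% (95% interval 4.62 to 6.77) against 3.17% (2.47 to 4.01). In pool 2 it was 24.6% (23.2 to 26.1) against 7.84% (6.91 to 8.85), and in pool 3 30.1% (28.0 to 32.2) against 4.02% (3.33 to 4.81). In pool 4 it was 30.2% (28.7 to 31.7) against 14.9% (13.7 to 16.1). The exact two-sided permutation test within libraries gave p = 0.125, the smallest that 16 arrangements allow, so the difference did not pass. Shares are of sorted nuclei and need not equal shares in bone.

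**Figure D1:**
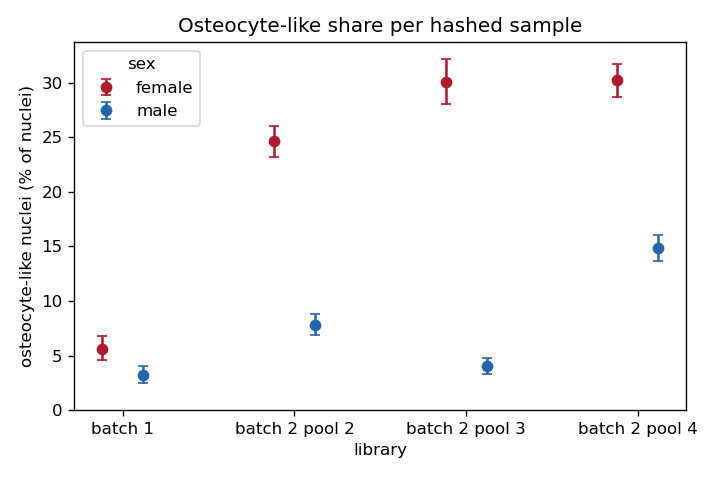
Osteocyte-like nuclei as a percent of all listed nuclei (y axis) in the female and male sample of each of 4 libraries (x axis), with 95% exact Clopper-Pearson intervals as bars. The female sample stands above the male one in each library, from 5.62% against 3.17% in batch 1 to 30.1% against 4.02% in pool 3.

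Neutrophil-like nuclei, raised in the granule genes Ltf, Ngp and Camp, were the fewer in female samples, at 12.8% ± 2.86 against 29.4% ± 8.32 (SD, n = 4 per sex), lower in 4 of 4 libraries. Erythroid-like nuclei, raised in haemoglobin genes, were also lower in 4 of 4, at 12.9% ± 9.36 against 20.1% ± 8.64, a difference of -7.21 points that lay between -11.8 and -3.97 when a sample was left out. Osteoblast-like nuclei, raised in Bglap (osteocalcin) and collagen I genes, stood at 4.91% ± 1.88 against 2.05% ± 1.46, endothelial-like at 3.58% ± 0.644 against 1.87% ± 0.344 and T or NK-like at 3.70% ± 0.260 against 2.81% ± 0.284, each higher in females in 4 of 4. The endothelial difference turned to -2.31 points as a share of non-haematopoietic nuclei, and the LepR stromal one to -8.60. Macrophage-like nuclei stood at 6.45% against 7.76%, osteoclast-like at 4.42% against 3.85%, B lymphoid-like at 7.33% against 6.88% and LepR stromal-like nuclei, marrow cells that secrete Cxcl12, at 2.54% against 2.41%. Leaving out a sample gave differences of -1.69 to -0.544 points for macrophage, 0.249 to 0.946 for osteoclast and -1.73 to 2.44 for B lymphoid shares. Of the authors' osteoclast-like nuclei, 113 in batch 1 and 201 in pool 3 lay among macrophage-like nuclei of the joint clustering. Only 25 and 15 lay among its osteoclast-like ones. In the libraries with counts the osteoclast difference was 0.602 points by joint clusters and -0.303 by the authors' clusters. An unnamed cluster of batch 2 whose closest list was that of osteoblasts was left out of the osteoblast share and held 9.78%, 6.85% and 7.40% of female and 7.09%, 1.85% and 5.34% of male nuclei in pools 2, 3 and 4. Another, closest to the B lymphoid list, held 8.55%, 6.42% and 9.01% of female and 2.84%, 6.12% and 4.99% of male nuclei there. Counted in, these clusters gave osteoblast shares of 10.9% ± 3.52 against 5.62% ± 3.11 and B lymphoid shares of 13.3% ± 1.02 against 10.4% ± 4.15 (SD, n = 4 per sex). The exact permutation test gave an adjusted p over 9 types of 0.225 for the neutrophil, erythroid, osteoblast, endothelial and T or NK shares. It gave 0.563 for macrophage, 0.643 for osteoclast, 0.703 for B lymphoid and 0.875 for LepR stromal shares, so none passed.

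Single genes that act on osteoclasts or rise in low oxygen were among those that differed between osteocytes and osteoblasts. Tnfrsf11b, which encodes osteoprotegerin, the decoy receptor that restrains osteoclast formation, stood at 259 ± 82.0 CPM in osteocytes and 25.7 ± 13.3 in osteoblasts (SD, n = 4), a log2 difference of 3.62 (SE 0.36). Tnfsf11, which encodes the osteoclast-forming ligand RANKL, stood at 3.89 ± 4.55 against 54.9 ± 11.9 CPM, a difference of -4.51 (SE 0.66), and Csf1, the macrophage growth factor, at 9.91 ± 6.84 against 317 ± 75.0 CPM, a difference of -4.71 (SE 0.29). Bnip3, a mitophagy gene induced in hypoxia, was higher by 3.86 (SE 0.27), and Cd44, a hyaluronan receptor, by 4.28 (SE 0.25). Outside the lists, the growth factor gene Fgf1 (5.47, SE 0.25), the deacetylase gene Hdac9 (4.92, SE 0.27) and the stress-response gene Ndrg1 (4.05, SE 0.22) were higher. The other leading higher genes were Gm52981 (10.1), Mapt (8.35), Gm9750 (8.24), Tg (6.23), Magi1 (5.66), Usp53 (5.19) and Zdhhc14 (4.59). The collagen gene Col5a1 (-5.81, SE 0.31) and the proteoglycan gene Dcn (-5.13, SE 0.28) were lower. The other leading lower genes outside the lists were Gm19299 (-9.51), Adamts18 (-8.76), Hs3st5 (-8.22), Gm20619 (-7.96), Fbn1 (-6.57), Olfml2b (-6.37) and Lifr (-4.60). Of these, Gm19299, Hs3st5 and Lifr were leading genes of the Mmp13-led joint cluster, which held 245 of 368 osteoblast-like nuclei. Sost (8.48), Mepe (6.99), Dkk1 (4.49), Phex (3.60), Pdpn (2.67) and Dmp1 (2.24), used to name the osteocyte cluster, stood higher by construction.

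By fixed list, osteocytes stood higher than osteoblasts in 7 and lower in 0 of 11 tested hypoxia and glycolysis genes, among them Ldha (1.56), which makes lactate, and Egln3 (3.76), an oxygen sensor. Of 4 osteoclast regulation genes 1 was higher and 3 lower, Cxcl12 (-3.75), a chemokine, being the other lower one. Of 7 perilacunar remodeling genes 1 was higher and 5 lower, among them the proteases Mmp13 (-6.65) and Mmp2 (-5.05). Ctsk (-4.38) and Acp5 (-3.42), also lower, are osteoclast markers whose osteoblast levels were highest in the batch 1 female sample, at 620 and 416 CPM against 72.4 and 23.5 in the pool 3 female one. Of 14 matrix and mineralization genes 3 were higher and 10 lower, with Smpd3 (-5.81), a sphingomyelinase needed for mineralization, Alpl (-8.37) and Bglap (-5.76) the lower ones named, the last pair also used to name osteoblasts. Of 18 hormone and growth factor receptor genes 4 were higher and 8 lower, including the parathyroid hormone receptor Pth1r (-1.95), Fgfr2 (-2.94) and the estrogen receptor Esr1 (-0.62). Esr1 lost its call in 3 of 4 fits that left out a sample, at -0.64 without the batch 1 male, -0.51 without the pool 3 female and -0.58 without the pool 3 male sample. Of 11 WNT genes 2 were higher, Sost and Dkk1, and 7 lower, such as the sclerostin receptors Lrp4 (-2.37) and Lrp5 (-1.67).

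Of 24 dendrite, cytoskeleton and axon guidance genes 5 were higher and 12 lower, the semaphorin receptors Plxna2 (-6.14) and Nrp1 (-3.90) among the lower. Of 11 mechanosensing genes 1 was higher, the calcium channel subunit Cacna2d1 (1.97), and 6 lower, among them the stretch-gated potassium channel Kcnk2 (-4.33). Osteocyte identity genes were higher in 9 and lower in 2 of 12. Circadian genes were higher in 5 and lower in 1 of 13, with Arntl (1.72) higher and Npas2 (-1.49) lower. Fasting genes were higher in 4 and lower in 3 of 13, among the lower Pdk4 (-3.60), which spares glucose. Senescence genes were higher in 2 and lower in 1 of 4, with the cell cycle inhibitor Cdkn1a (1.74) higher and Igfbp5 (-4.58) lower. Immediate early genes were higher in 1 and lower in 2 of 6, with Jund (1.21) higher and Egr1 (-1.46) lower. Oxidative phosphorylation genes were higher in 0 and lower in 3 of 14, granulocyte genes higher in 2 and lower in 0 of 6 (Camp 0.86, S100a9 0.81), and of 4 erythroid, 4 Y-linked and 10 X inactivation genes 0 passed. Without the pool 3 female sample Egr1 (-1.01), Camp (0.67) and S100a9 (0.68) lost their calls, and Camp (0.70) and S100a9 (0.72) also did without the batch 1 male sample. No muscle gene was tested. Adjusted over the list alone the counts were the same, except 4 higher matrix genes, 4 lower fasting genes, and 1 higher and 5 lower oxidative phosphorylation genes.

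The osteoblast-like sums held 103 female and 64 male nuclei in batch 1 and 154 and 47 in pool 3. Of these, 65, 45, 94 and 41 lay in a joint cluster led by Mmp13 and Tnc, with Lifr, Hs3st5 and Gm19299 also among its 10 leading genes, and 136 of the pool 3 nuclei lay in the cluster of batch 2 closest to osteoblasts that was left unnamed for shares. In edgeR, 2846 of 9428 genes passed between osteocytes and osteoblasts, 1387 higher and 1459 lower, with 1818 when the pool 3 female sample was left out. Camera called hypoxia genes (adjusted p = 0.0109; adjusted p = 0.406 with an estimated correlation) higher and perilacunar genes (adjusted p = 0.0183; adjusted p = 0.406 with an estimated correlation) lower. It also called osteocyte identity genes (adjusted p = 0.00288; adjusted p = 0.406 with an estimated correlation) higher, all 13 of which are markers that named the osteocytes, and matrix genes (adjusted p = 0.0109; adjusted p = 0.413 with an estimated correlation) lower, 8 of 16 of which are markers that named the osteoblasts, so both calls restate the naming in whole or in part. Mmp13, a lower perilacunar gene, led the joint cluster that held most osteoblast-like nuclei. The perilacunar call is thus also tied in part to the clustering. Of the lists that camera did not call, dendrite genes came nearest (adjusted p = 0.0783), with 0.126 for osteoclast regulation genes. Fry, which asks only whether a list's own genes differ, called the same 4 lists and also mechanosensing (adjusted p = 0.00224), hormone receptor (0.00989), osteoclast regulation (0.0194), dendrite (0.0267) and WNT genes (0.0330) lower and senescence genes (0.0137) higher. Median and mean differed in sign for fasting (0.13 and -0.40), senescence (0.37 and -0.38) and Y-linked genes (-0.19 and 0.03). Both types were drawn from the same counts, so these p-values are too small and serve to rank genes.

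**Figure D2:**
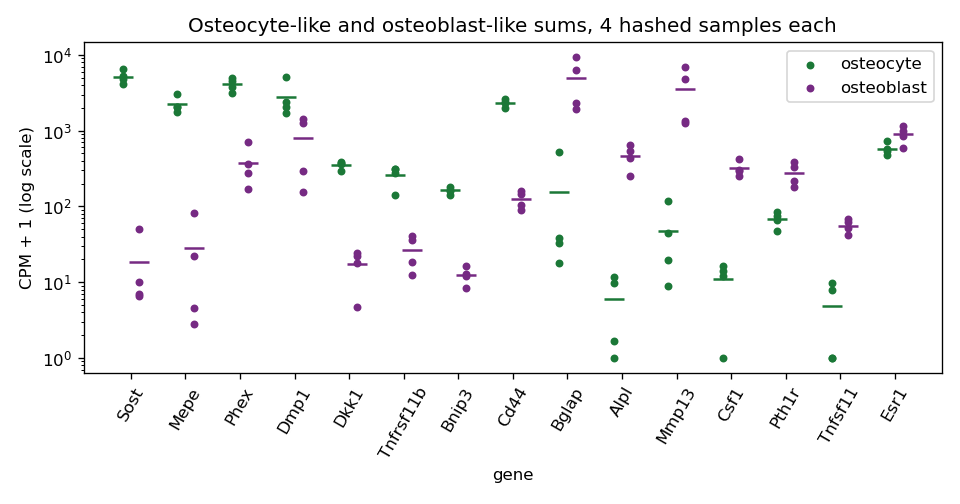
Levels of 15 genes in CPM plus 1 on a log axis (y axis) in osteocyte-like and osteoblast-like nuclei, with a dot for each of 4 samples and a line at the mean. Tnfrsf11b has a mean of 259 CPM in osteocytes and 25.7 in osteoblasts, and Tnfsf11 means of 3.89 and 54.9.

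Against the mean of the other types, most of them haematopoietic, osteocytes stood high in clock, hormone receptor and WNT genes. The comparison with osteoblasts did not show the same. There 4 of 18 hormone receptor genes were higher and 8 lower, and 2 of 11 WNT genes were higher and 7 lower. Camera did not call circadian genes there (adjusted p = 0.248). Tnfrsf11b stood at 264 ± 90.5 CPM (SD, n = 4) in osteocytes and at 27.3 CPM in osteoblasts, the highest other type, a log2 difference of 8.17 (SE 0.26) from the mean of other types. Wnt5b, a WNT ligand, stood at 858 ± 386 CPM against 126 in osteoblasts (6.69, SE 0.14), Ccn4, a matricellular WNT target, at 1365 ± 370 against 340 (8.15, SE 0.16), and Bnip3 at 163 ± 9.48 against 12.0 (4.41, SE 0.21). Cdkn1a stood at 159 ± 56.1 against 52.9 CPM in osteoblasts (5.36, SE 0.23). Sp100, a nuclear body gene, (-3.28, SE 0.20), Dock8, an immune cell migration gene, (-2.66, SE 0.20) and Akap13, a signalling scaffold, (-2.07, SE 0.15) were lower. Dmp1, Sost, Phex, Mepe, Pdpn and Dkk1 stood higher by 7.75 to 9.16, by construction. Tnfsf11 differed by -0.03 (SE 0.15) and was not called, with values from -1.48 to 1.65 when a sample was left out. Fgf23, the phosphate hormone secreted by osteocytes, had a UMI in 0 of 848 osteocyte nuclei, which allows a share of up to 0.354% of nuclei with a UMI.

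By fixed list, circadian genes were higher than the mean of other types in 12 and lower in 0 of 13, among them Per3 (2.92), Nr1d2 (2.33) and Per1 (2.68), although Nr1d2 stood at 176 CPM in osteocytes and 180 in LepR stromal nuclei and Per3 at 125 against 144. Hormone and growth factor receptor genes were higher in 12 and lower in 3 of 18. Fgfr1 (6.27) and the thyroid hormone receptor Thrb (3.56) stood highest in osteocytes, whereas the vitamin D receptor Vdr (4.16) stood at 165 CPM against 422 in osteoblasts and the growth hormone receptor Ghr (4.09) at 727 against 5276 in LepR stromal nuclei. Esr1 (2.22) stood at 587 CPM against 977 in osteoblasts. WNT genes were higher in 9 and lower in 0 of 12, with the antagonist Wif1 (5.52) at 333 CPM against 336 in osteoblasts and Lrp4 (3.58) at 231 against 1252. Dendrite and axon guidance genes were higher in 15 and lower in 2 of 24, with Cd44 (3.40) highest in osteocytes, whereas the guidance cues Slit2 (5.86) and Slit3 (5.95) were highest in osteoblasts. Matrix and mineralization genes were higher in 12 and lower in 3 of 15, among them the casein kinase Fam20c (6.18) and the pyrophosphate genes Ank (3.86) and Enpp1 (4.32). Hypoxia genes were higher in 8 and lower in 2 of 11 (Vegfa 2.64, Ldha 1.75), and oxidative phosphorylation genes higher in 1 and lower in 8 of 15 (Cox5a -1.10, Cycs -1.40).

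Osteocyte identity genes were higher in 12 of 12. Mechanosensing genes were higher in 7 and lower in 3 of 13, with the gap junction gene Gja1 (4.34) at 489 CPM against 1001 in osteoblasts. Fasting genes were higher in 7 and lower in 2 of 13 (Klf9 3.07, Cpt1a -1.77), immediate early genes higher in 4 and lower in 2 of 11 (Jund 1.43, Ier2 -1.14), senescence genes higher in 2 and lower in 2 of 6 (Cdkn2c -2.15), perilacunar genes higher in 3 and lower in 2 of 8 (Mmp14 4.64, Car2 -1.78), and osteoclast regulation genes higher in 1 and lower in 1 of 5 (Tnfrsf11b 8.17, Cxcl12 -1.85). The pH regulator Slc4a2 (0.76) and Mmp2 (1.39) lost their calls without the pool 3 female sample, at 0.016 and 0.79. Erythroid genes were lower in 4 of 4 (Hba-a2 -1.57), X inactivation genes higher in 1 of 10 (Jpx 0.67, not called at 0.56 without the pool 3 female or 0.54 without the pool 3 male sample), and of 6 granulocyte, 4 Y-linked and 2 muscle genes 0 passed. Adjusted over the list alone, dendrite genes were higher in 16 and oxidative phosphorylation genes lower in 9, with the other counts the same.

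In edgeR, 6192 of 12383 genes passed against the mean of the other types, 3365 higher and 2827 lower, over 11 types in 4 samples. Camera calls that held with an estimated correlation were circadian genes (adjusted p = 1.36e-05; adjusted p = 0.00138 with an estimated correlation) and hormone receptors (adjusted p = 0.000102; adjusted p = 0.00682 with an estimated correlation). WNT genes (adjusted p = 0.00128; adjusted p = 0.00984 with an estimated correlation) and dendrite genes (adjusted p = 0.00106; adjusted p = 0.0343 with an estimated correlation) also held, 3 of 18 and 2 of 26 of them markers of the osteocyte cluster. Identity genes (adjusted p = 6.73e-14; adjusted p = 6.33e-06 with an estimated correlation) held by construction, as all 13 are such markers. Matrix genes (adjusted p = 0.00106; adjusted p = 0.198 with an estimated correlation), hypoxia genes (adjusted p = 0.0134; adjusted p = 0.153 with an estimated correlation) and the lower oxidative phosphorylation genes (adjusted p = 0.0240; adjusted p = 0.433 with an estimated correlation) did not. Fry called all of these and also osteoclast regulation (adjusted p = 0.00910), mechanosensing (6.04e-08), fasting (0.0321) and senescence genes (4.06e-07) higher and erythroid genes (0.000183) lower. Median and mean differed in sign for osteoclast regulation (-0.44 and 0.97) and Y-linked genes (-0.035 and 0.066). The types were drawn from the same counts, so here too p-values serve to rank genes.

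Between female and male osteocytes, 5 genes passed in edgeR, all sex-linked. The sums held 99 female and 54 male nuclei in batch 1 and 577 and 118 in pool 3, with 228091, 85312, 3267413 and 613332 UMIs in that order. Xist stood at 1825 ± 548 CPM in female and 38.9 ± 32.2 CPM in male samples (SD, n = 2 per sex), a log2 difference of 6.33 (SE 0.49). Uty, a histone demethylase gene on the Y chromosome, was lower by -6.18 (SE 0.43), Ddx3y, an RNA helicase gene, by -6.19 (SE 0.52) and Eif2s3y, a translation factor gene, by -6.37 (SE 0.64), and Kdm5d stood at 0.496 CPM in female and 60.3 CPM in male samples. Osteocyte genes did not pass, with female minus male differences of 0.60 (SE 0.26) for Dmp1, -0.09 (0.26) for Sost, -0.46 (0.24) for Mepe, 0.14 (0.26) for Dkk1, 0.19 (0.32) for Tnfrsf11b, -0.20 (0.26) for Esr1 and 0.16 (0.48) for Pdpn. Phex stood at 4393 ± 780 CPM in female and 4376 ± 1024 CPM in male samples. The log2 differences within batch 1 and pool 3 had opposite signs for Pdpn (2.44 and -0.58), Tnfrsf11b (1.06 and -0.23) and Sost (-0.51 and 0.31). So they did for Dkk1 (-0.04 and 0.26), Esr1 (0.19 and -0.47) and Phex (0.44 and -0.41). Dmp1 (0.99 and 0.22) and Mepe (-0.66 and -0.26) kept their sign.

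Outside the sex-linked lists, 0 genes passed in edgeR and DESeq2 called 2, S100a9 and Tgfb2. Of all 6337 genes tested, sex-linked ones included, 237 had an unadjusted p under 0.05 in edgeR where chance gives 317. Of genes higher in females, low p values belonged to Kcnip4, a potassium channel partner, at 296 ± 144 CPM in females and 22.4 ± 31.7 in males (2.68, SE 0.49, adjusted p = 0.139), and Sema7a, a membrane semaphorin, at 305 ± 65.0 against 94.3 ± 11.3 (1.53, SE 0.31, adjusted p = 0.190). Slc13a5, a citrate transporter gene, stood at 78.1 against 0.897 CPM, the glutamate receptor gene Grm8 at 58.4 against 0.897 CPM and the catenin gene Ctnnd2 at 49.7 against 7.07 CPM. Grm8 and Ctnnd2 were also among the 10 leading genes of the dendritic-like cluster. Lower values were seen for the neutrophil alarmin S100a9, at 370 ± 133 against 1668 ± 1514 CPM (-1.79, SE 0.33, adjusted p = 0.139), Retnlg, another neutrophil gene (-2.83, SE 0.54), the growth factor Tgfb2, also among the 10 leading genes of the osteocyte cluster, at 1296 ± 224 against 3156 ± 212 CPM (-1.28, SE 0.25, adjusted p = 0.177), Lcn2 (-2.11, SE 0.44) and the globin Hba-a1 (-1.30, SE 0.29). The sign of female minus male was the same in both libraries for 51.8% of 6323 genes, and Pearson's r between the libraries was 0.0477 across genes, which are not independent replicates. The count rose to 48 without a filter on low counts, 31 without Scrublet doublets, which left 574 of 577 female and 115 of 118 male nuclei in pool 3 and all in batch 1, and 34 with osteocytes by the authors' clusters, of which 42, 26 and 28 lay outside the sex-linked lists. With 54 nuclei in every sample 5 genes passed, 3 sex-linked ones and, outside those lists, Kcnip4 and Mdga2, while Eif2s3y and Kdm5d lost their calls. With 1 residual degree of freedom, 5% of simulated 4-fold changes were found at a dispersion of 0.1 set for every gene. That dispersion was not matched to the real counts. In the real fit the SE was 0.26 for Dmp1 and 0.88 for Slc13a5, so power differed between genes. Differences of 4-fold may have gone undetected above all in genes with a large SE.

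By fixed list, matrix and mineralization genes leaned towards females with a median log2 difference of 0.98 over 11 genes, such as Bglap (2.25) and Spp1 (0.98), which encodes osteopontin. Granulocyte genes leaned towards males with a median of -1.58 over 6 genes, and erythroid genes with -1.05 over 4. The medians were larger in batch 1 than in pool 3, at 0.81 and 0.42 for matrix, -2.65 and -0.61 for granulocyte and -1.34 and -0.74 for erythroid genes (log2 ratios of CPM plus 10). None of these passed over all genes, and adjusted over the list alone 6 matrix genes were higher, and 6 granulocyte and 3 erythroid genes lower. Camera called matrix (adjusted p = 0.000205), granulocyte (7.05e-07), erythroid (0.000205), Y-linked (5.49e-14) and X inactivation genes (0.000230). All 5 were lost, at adjusted p = 0.937 with an estimated correlation, and fry gave adjusted p = 0.673, 0.715, 0.628, 0.185 and 0.185 in that order. With an estimated correlation camera tests on the residual degrees of freedom, of which there was 1. The Y-linked list had an estimated correlation of 0, yet its unadjusted camera p rose from 3.43e-15 to 0.0791. The loss of a call thus does not decide whether a list differs.

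No camera call was made for the other lists, whose adjusted p was 0.83 for osteocyte identity (Tnc -0.96), hormone receptor (Thrb -0.66), mechanosensing (Itgb1 -0.24), fasting (Fkbp5 1.62), circadian (Cry2 -0.57) and immediate early genes (Jund -0.67), 0.966 for hypoxia (Vegfa 0.49), 0.720 for WNT (Lrp5 0.44), 0.446 for perilacunar (Mmp13 -1.40), and 0.498 for both dendrite genes and oxidative phosphorylation genes (Cox4i1 0.91). Osteoclast regulation and senescence lists had 2 tested members each, with 0 passing (Cxcl12 0.08, Cdkn1a 0.51), and muscle RNA had 0. Adjusted over the list alone, 1 identity gene was lower, 1 perilacunar gene lower, 1 fasting gene higher and 3 dendrite genes higher, with 0 in WNT, mechanosensing, hormone receptor, circadian, immediate early, hypoxia and oxidative phosphorylation lists. The median and the mean differed in sign for perilacunar (0.11 and -0.33) and identity genes (0.0038 and -0.020).

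The sex effect differed between osteocyte and erythroid nuclei for 7 of 11700 genes in edgeR, 5 higher and 2 lower. Col1a1, a chain of collagen I, had an interaction of 2.50 (SE 0.51, adjusted p = 0.00452), with 5306 CPM in the female and 137 in the male osteocyte sample of batch 1, against 470 and 368 in pool 3. Sparc, a collagen-binding protein, had 2.29 (SE 0.54), with 918 against 58.8 and 232 against 139 CPM. Retnlg had -3.25 (SE 0.51), with 19.4 against 614 and 31.0 against 84.1 CPM. Ghr had -2.38 (SE 0.56). Its osteocyte levels went opposite ways, at 399 CPM in the female against 516 in the male sample of batch 1 and 636 against 500 in pool 3. Its erythroid levels were low, at 36.6 against 6.93 and 18.6 against 4.36 CPM, so the value rests largely on erythroid nuclei. Robo2, an axon guidance receptor, Grm8 and Gria3, a glutamate receptor subunit, completed the 7. CPM in this comparison were scaled over osteocyte and erythroid sums together, so they are not on the scale of the CPM in other comparisons. Grm8 and Gria3 were among the 10 leading genes of the dendritic-like cluster. An unadjusted p under 0.05 was reached by 274 genes, and 16 genes passed with DESeq2 size factors. The p-values of the 7 genes were close to normal-tail values of the log2 difference over its SE, although the fit left 2 residual degrees of freedom. A gene's own spread between the libraries, wide for Col1a1, was thus hardly weighed, and these calls are less firm than their p-values.

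Among other types, macrophage-like and osteoblast-like nuclei held most genes that differed between the sexes in edgeR. In macrophage-like nuclei Atp6v0d2, a proton pump subunit raised in osteoclasts, stood lower at 53.4 CPM in females against 268 in males (log2 -2.34, SE 0.19, n = 2 per sex), and Nr4a1, an immediate early receptor gene, was higher at 74.6 against 29.9 (1.30, SE 0.24). The osteoblast genes Col1a1 (1.53), Col1a2 (1.35), Sparc (1.64) and Bglap2 (2.33) were also higher in these nuclei, and the granulocyte genes S100a9 (-0.79), S100a8 (-0.70), Ltf (-1.14) and Ngp (-0.89) lower. In osteoblast-like nuclei Ibsp, a mineral-binding matrix protein (1.35, SE 0.32), Acp5, an osteoclast phosphatase (2.82, SE 0.36), and Phex (1.29, SE 0.30) were higher in females, and Wif1 (-1.03, SE 0.24), Klf9, a glucocorticoid-induced factor (-1.04, SE 0.24), and the granulocyte gene S100a8 (-1.76, SE 0.25) were lower. In B lymphoid-like nuclei the mineralocorticoid receptor Nr3c2 was higher (1.38, SE 0.19) and Esr1 lower (-0.56, SE 0.14), and in LepR stromal-like nuclei Phex was higher at 342 against 47.9 CPM (3.21, SE 0.41). These listed genes were chosen after their values were seen. Of the macrophage-like nuclei, 113 in batch 1 and 201 in pool 3 lay in clusters of the authors that were osteoclast-like. The genes passing outside the sex-linked lists numbered 147 higher and 85 lower in macrophage-like, 78 and 74 in osteoblast-like, 17 and 35 in B lymphoid-like, 13 and 5 in LepR stromal-like, 7 and 0 in mast-like, 6 and 1 in neutrophil-like, and 2 and 2 in T or NK-like nuclei. None passed in dendritic-like, endothelial-like and erythroid-like nuclei in edgeR, with 186, 270 and 211 at an unadjusted p under 0.05. The sum over 10 types was 472, against 95 with DESeq2 and 1091 without a filter on low counts. Median prior degrees of freedom were 27.8 in macrophage-like, 17.1 in osteoblast-like and 10.9 in osteocyte-like nuclei, all at 1 residual degree of freedom, and whether sex effects differed between these types was not tested. Subclusters pooled in a type were unevenly held, as in the Bglap-led osteoblast cluster with 38 of 103 female and 19 of 64 male nuclei in batch 1 and 60 of 154 and 6 of 47 in pool 3. The Adgre4-led macrophage cluster held 48 of 163 female and 33 of 218 male nuclei in batch 1. In pool 3 it held 58 of 189 and 36 of 414. Adgre4 itself was among the genes passing in macrophage-like nuclei. A different mix of subclusters and a sex difference within them were not told apart in these calls.

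Between batch 1 and batch 2 only values were compared, since batch and library coincide. Osteocyte shares were 5.62% and 3.17% in batch 1 and at least 24.6% in females and 4.02% in males of batch 2. Bglap stood at 562 CPM in female and 37.0 in male osteocytes of batch 1, against 37.4 and 17.9 in pool 3, and Spp1 at 2121 and 1184 against 341 and 156. S100a9 stood at 464 and 2739 CPM against 276 and 598. Sost stood at 5244 and 7464 CPM in batch 1 and at 5324 and 4280 in pool 3.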

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

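The tests on the osteocyte share, on its denominator, its depth and its hashtags, were chosen only after that share had been seen, and those on marrow RNA and matrix genes after the list results but before the values they measure. Of 20 groups of 4 samples tested for a sample far from the others, 2 stood out, and chance flags about 1 in 20 groups. The B lymphoid-like share of the batch 1 female sample, 13.8%, lay far above the other female samples, but not once an unnamed cluster of batch 2 closest to the B lymphoid list was counted in, which gave these 14.2%, 11.9% and 13.3%. The macrophage-like share of the pool 2 male sample, 10.1%, lay far above the other male samples. Macrophage-like nuclei were also more frequent in the female sample by 0.335 points in batch 1 and less frequent in all 3 pools of batch 2, at 6.36% against 10.1%, 5.20% against 6.85% and 6.66% against 6.89%, a difference between batches that was not tested.

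The sex effect differed between osteocyte and erythroid nuclei for 7 genes by the interaction test, which hardly weighed a gene's own spread between libraries. The log2 difference was -3.25 for Retnlg, 2.50 for Col1a1, 2.29 for Sparc, -2.38 for Ghr, 6.77 for Robo2, 5.52 for Gria3 and 9.06 for Grm8. The value for Grm8 rests on 0 and 1.31 CPM in male osteocyte samples and that for Robo2 on 0 CPM in both female erythroid samples, so neither is a bound. That for Ghr rests largely on low erythroid levels, as its osteocyte levels differed in opposite directions in batch 1 and pool 3.

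Barcodes outside the authors' tables held UMIs of genes high in osteocytes. Of 6089 such barcodes in batch 1, 5042 had most hashtag counts from a tag without a sample, and of 10152 in pool 3, 9538 did. In those led by such a tag Sost stood at 160 CPM, Dmp1 at 271 CPM and Phex at 159 CPM in batch 1, and at 145, 121 and 184 CPM in pool 3. Among the other named types the highest means were 60.7 CPM for Sost, in erythroid-like nuclei, and 817 for Dmp1 and 412 for Phex, in osteoblast-like ones. The barcodes lay below these for Dmp1 and Phex and above the highest mean for Sost. The means of named types were TMM scaled and those of the barcodes were not. A mean over mixed barcodes does not show which of them hold the RNA. Osteocyte nuclei, other cells and free RNA thus stay open as sources for all of these genes. The title of the pool 3 library names young and old bone, but the mapping does not say what these tags mark. These barcodes belong to no sample in the mapping and entered no comparison.

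The higher osteocyte share of female samples was weighed against 3 technical explanations. More haematopoietic nuclei in male samples as the whole cause were argued against by the osteocyte share of non-haematopoietic nuclei. It was higher in females by 13.3 points (SE 4.63) and in 4 of 4 libraries, though by 2.67 points only in batch 1. That denominator keeps LepR stromal nuclei, which are marrow cells, and endothelial nuclei, whose shares of it differed by -8.60 and -2.31 points. More marrow nuclei of all kinds as the whole cause thus stay open. Loss of shallow nuclei as the whole cause was argued against by nuclei at or above the median depth of their library. There females were higher by 9.29 points (SE 4.21) and in 4 of 4 libraries, though by 0.608 points only in batch 1. This argument and that on haematopoietic nuclei are weak, as both rest on a mean above 2 SE over 4 libraries. The exact permutation test within libraries gave p = 0.125 for the share of non-haematopoietic nuclei, the smallest it allows. An exchange of hashtags was argued against by Y-linked UMIs in batch 1 and pool 3. At most 3.99% of female-tagged osteocyte nuclei held one, against at least 51.9% of male-tagged ones. In pools 2 and 4 an exchange stays open, as no gene counts were analysed there. Neutrophil and erythroid shares were lower in females in 4 of 4 libraries, so these nuclei may account for part of the higher osteocyte share. A difference in dissection or sorting between the 2 samples of a library and a difference between the sexes stay open as untested.

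Granulocyte and erythroid RNA lower in female osteocytes may come from free RNA of the more numerous marrow cells in male samples, although the bones were flushed of marrow. Abundant members of these lists were S100a9, at 370 CPM in female and 1668 in male osteocytes, and Hbb-bs, at 384 and 970. The same 10 genes had a median log2 female over male ratio of -0.917 (SE 0.410) in endothelial, T or NK and LepR stromal nuclei, and 5 of 6 medians by type and library were negative, with 1.01 in batch 1 endothelial nuclei the exception. That SE is taken over those 6 medians, which come from the same pairs of samples and are not independent. In endothelial nuclei all 4 globin genes were higher in females in both libraries, such as Hba-a1 at 1.55 in batch 1 and 0.83 in pool 3, so free erythroid RNA is less clear than free granulocyte RNA. For genes called between the sexes outside the sex-linked lists this could not be tested, since edgeR called 0 and DESeq2 2. Without a filter, without doublets and by the authors' clusters edgeR called 42, 26 and 28, of which 7, 4 and 7 were granulocyte or erythroid and 6, 3 and 2 matrix genes. A difference between the sexes stays open as untested.

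Matrix and mineralization genes leaning towards females may come from osteoblast nuclei or doublets in the osteocyte cluster, from free osteoblast RNA, or from a difference between the sexes. The first stays open. The 12 osteoblast genes outside the list had a median of 0.42 in osteocyte sums, with 11 above 0, between the bounds set for and against it. Its SE, 0.14, was bootstrapped over genes and leaves out the spread between samples. The second stays open too, since the list's genes had a median of 0.0917 (SE 0.191) in T or NK, B lymphoid and erythroid nuclei, an error too wide to exclude it. That SE is taken over medians by type and library, which share samples and are not independent. By type the median was 1.05 in T or NK, -0.249 in B lymphoid and -0.0810 in erythroid nuclei of batch 1 and 0.258, 0.492 and 0.0680 in those of pool 3. Col1a1 (1.53), Col1a2 (1.35), Sparc (1.64) and Bglap2 (2.33) were higher in female macrophage-like nuclei, so the values go both ways. A difference between the sexes was not tested apart from these.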

How the results depend on the processing

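Osteocyte nuclei by the authors' clusters, joint clusters and authors' clusters in the libraries with counts, shares with unnamed clusters counted under their closest list, and the sex test in other types were chosen only after the data had been seen. Of alternatives to the comparisons and shares 137 kept their direction and side of the threshold, or stayed within 1.5 times the count, 12 reversed, 7 moved and 1 weakened, and of those to single genes and lists 1819 were the same, 18 reversed, 48 gained and 34 lost a call and 26 moved. Shares permuted within libraries could not pass in any setting, as p cannot fall under 0.125. The minimum of 50 nuclei left the same osteocyte samples. Such alternatives could not change side, so the tally overstates how firm the results are. The count of osteocyte sex genes, 5, became 48 without a filter on low counts, 31 without Scrublet doublets and 34 by the authors' clusters. The interaction count of 7 became 16 with DESeq2 size factors. Calls between the sexes in other types, 472, became 1091 without a filter and 95 with the DESeq2 Wald test. The 5 lists called became 0 with an estimated correlation, a test on 1 residual degree of freedom that lost even the Y-linked list and so decides little. Leaving out a sample gave 1818 to 2526 genes between osteocytes and osteoblasts, the lowest without the pool 3 female sample, against 2846, and 4944 to 5884 against other types. The osteocyte share difference stayed between 12.6 and 20.8 points when a sample was left out, with exact permutation p from 0.125 to 0.250, and permutation over all samples gave p = 0.0857. Other shares that reversed were B lymphoid, at -1.73 to 2.44 points leaving out a sample, -0.228 by joint clusters and -0.894 by authors' clusters in the libraries with counts, and LepR stromal, at -0.354 to 0.390, -0.390 and -0.131 in the same order and -8.60 of non-haematopoietic nuclei. Erythroid shares, at -7.21 points, ranged from -11.8 to -3.97 leaving out a sample and were -4.77 by joint clusters, where the neutrophil difference of -16.5 became -10.5. Endothelial shares reversed to -2.31 with that denominator and osteoclast shares to -0.303 in the libraries with counts. Female minus male values near 0 reversed for Cxcl12 (-0.77), Sost (0.14), Jpx (-0.022) and Eif2s3x (-0.11) by the authors' clusters, Phex (-0.40), Dkk1 (-0.10) and Eif2s3x (-0.0069) with equal nuclei, Slc4a2 (-0.024) with DESeq2, and Phex with size factors (-1.8e-05), with at least 1000 UMIs (-0.018) and without doublets (-0.0061). Leaving out a sample moved Kdm5d between osteocytes and osteoblasts from -0.57 to 0.11, and against other types Ttn from -2.05 to 0.18 and Tnfsf11 from -1.48 to 1.65. Tnfsf11 also reversed with size factors (0.0044), DESeq2 (0.53) and a library term (0.014). The cause was not tested. Female and male samples were compared within libraries, and 4 genes were called without a library term. No paired analysis was possible between expression and hashtag libraries, whose labels share numbers, because those with the same number hold different measurements of the same nuclei. Leaving out a sample left no residual degrees of freedom for sex tests, which then gave values only. Each library alone, an age term, old against young, and subtypes were not run. Depth was uneven in the sex test, with 85312 UMIs in the batch 1 male osteocyte sample against 3267413 in the pool 3 female one. With 54 nuclei in every sample Eif2s3y and Kdm5d lost their calls, and Kcnip4 and Mdga2 gained one.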

Other observations

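The test of splits for other types used 24 draws, a number chosen only after the fit had been timed. Tnfsf11 stood at 67.9 CPM in LepR stromal-like, 58.7 in osteoblast-like, 13.5 in T or NK-like and 3.95 in osteocyte-like nuclei (means, n = 4). Skeletal muscle-like nuclei, raised in Ttn and Neb, numbered 222 with a median of 1225.5 UMIs. A cluster of 37 erythroid-like nuclei had Mepe as its leading gene. Of nuclei in the authors' osteoclast-like clusters, 113 in batch 1 and 201 in pool 3 fell among macrophage-like nuclei of the joint clustering, and 25 and 15 among osteoclast-like ones. Of 848 joint osteocyte nuclei, 151 in batch 1 and 680 in pool 3 were also osteocyte-like by the authors' clusters.

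Chance was tested by exchanging type names among the sums. Between osteocytes and osteoblasts only 8 splits part every pair of sums of a sample, too few for a share under 0.05, and 1 of 8 gave as many genes, the real one with 2846, while the highest other gave 0. Against the other types, 1 of 24 splits gave as many genes, the real one with 6192, and the highest other gave 258. The types were clustered from these same counts, so the real names were bound to give the most and neither test says whether chance played a part.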
